A study of Rattus norvegicus with 8 samples.

How the data were processed

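RNA from primary rat nucleus pulposus cells was sequenced in 8 libraries. The nucleus pulposus is the gelatinous core of the intervertebral disc, a tissue whose cells live at high osmolarity. Per the labels, the cells grew out of tissue explants, were transduced with a control vector (PLKO1) or with a short hairpin RNA against TonEBP, and were then kept for 8 h in medium with 110 mM of added NaCl. TonEBP is the tonicity-responsive transcription factor encoded by Nfat5. The groups were 4 control libraries and 4 TonEBP knockdown libraries, taken from the sample titles, and each title also carries a Set number from 1 to 4 that occurs once in each group. Both groups received the added salt, so the design compares cells with more and with less TonEBP under hypertonic culture and holds no culture without added salt.

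Libraries were single reads of 50 cycles from an Illumina HiSeq instrument, per the labels. Per the submitters' processing notes, the tools named were Novoalign 2.08.01 and DESeq2 1.10.1 and the genome build named was rn5. The role of each tool, the annotation, the read counter and its use of strand are not given in the sources used here. The deposited signal values are one column per library of what the file headers call normalized values, for 13613 genes with Ensembl identifiers and symbols. Within each column every value was a whole multiple of the smallest one above 0, so each value is a read count that the authors divided by a factor for its library. The reads recovered in this way were whole for 100% of the values, within 0.001 reads, and the factors equal DESeq2's median-of-ratios size factors with a largest relative difference of 3.55e-15. The lowest sum of reads over the 8 libraries among the listed genes was 13, so genes with fewer reads are not analysed here. The deposited log2 fold changes are the authors' own, knockdown over control, per the file headers. They correlate across genes at 0.999 with those of DESeq2 with a prior and with the Set as a block, and at 0.960 without the block. With the block 1126 of its 1135 calls are also called in the authors' deposited table, and without the block 161 of its 162. The authors' table calls 1140 genes, and the fit with the block shares far more of them. The authors' calls therefore stand nearer to a paired test than to one without the Set. The deposited fold changes lie closer to 0 than the ratios of the deposited values for genes with few reads. They can also lie closer to 0 for abundant genes that vary between libraries, such as Ccl2, at log2 -1.32 in the authors' deposited table and -1.76 in limma. The deposited adjusted p-values are also the authors' own, with no adjustment method stated, and have no value for 1362 genes. Counting could not be checked for reads shared between paralogs or overlapping genes, which includes the chemokine family.

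The deposited file holds normalized values in place of raw counts, and the design fixed for that case was followed: limma 3.58.1 with a mean-variance trend on log2(value + 1), with group as the only term, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates changes of genes with few reads. Genes were kept by edgeR's filterByExpr on the recovered reads, which left 12383. Standard errors are limma's moderated ones. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test) called 1 gene without the Set and 0 with it. DESeq2 1.42.0 called 68 higher and 95 lower genes without the Set, and 518 higher and 656 lower with it. All tests ran in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Values for a group are means ± SD of normalized counts over its 4 libraries unless stated otherwise. CPM values are relative to the reads on the listed genes.

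Gene groups were tested with camera (preset correlation of 0.01), again with an estimated correlation, and with fry. The lists, 14 pathway lists and 7 marker lists for cell types or RNA quality, held 461 entries, of which 398 matched a symbol in the file. Camera compares a list with all other genes, and adjustment ran over the 21 lists. Fry asks whether the genes of a list move on balance one way. Counts adjusted over the list alone used limma's p-values of its members.

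The lists, the main tests, the rule for genes named in the text and most alternatives were chosen before the data were examined. Chosen after the data were seen were DESeq2, limma-voom, fry and camera with an estimated correlation, each with the Set as a block, the looser threshold of 0.10, edgeR with TMM and without the block, TMM in limma, other scalings for the lists, and the lists without both libraries of a Set. That rule takes Nfat5 and 10 fixed genes reported whatever their value. It adds the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a symbol, a mean of at least 1 CPM and no overlap between the groups. From each list it takes up to 4 members with the lowest adjusted p under 0.05, or the member with the lowest p where none passed. It also takes the 3 genes with the lowest adjusted p. Because limma without the Set called a single gene, the same rule was applied a second time to the authors' calls, a step decided after the data were seen. This named 78 genes. Members beyond these are named in the text where a list has few calls in the authors' deposited table or where the stress genes are described by branch, and were chosen after their values were seen. Of the fixed genes, Slc5a3, Hspa1b and Acan are not analysed here.

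Whether the Set numbers pair the libraries was checked before any calls were compared. Deviations from the group means over 10570 genes correlated between the control and the knockdown library of the same Set at 0.824, 0.787, 0.685 and 0.722, while the highest correlation between different Sets was 0.352. By that measure the numbers pair the libraries. What a Set is (an animal, a litter or a culture day) is not stated in the labels, and the columns of the file were matched to libraries by their group name and number. The Set explained on average 60.7% of a gene's variance and the group 18.7%. These shares are not adjusted for the number of levels, and with more levels the Set would get the larger share by chance alone. No pair of replicates came close to sampling noise, with a chi-square per degree of freedom from 66.9 to 249, so each library was counted once. Nothing in the labels says that libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may in part be technical.

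The tests were tried on simulated counts for this comparison, drawn for the 12383 genes with the real means, library sizes and differences between Sets, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes had a mean of at least 50 normalized counts, so recovery of genes with fewer reads was not measured. Limma without the Set recovered 3 of the 2-fold and 59 of the 4-fold genes with 0 false calls. With the Set as a block it recovered 68 and 99 with 8 false calls. EdgeR recovered 1 and 51 with 0 false calls, and with the block 69 and 100 with 10 false calls. DESeq2 recovered 31 and 90 with 0 false calls, and with the block 79 and 99 with 35 false calls. Limma-voom with the block recovered 71 and 100 with 10 false calls. For DESeq2 with the block the 35 false calls stood beside 178 true ones, a larger share than the threshold of 0.05 aims at. The authors' calls stand near a fit of this kind, but their own fit was not simulated.

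Alternatives covered the scaling between libraries (DESeq2 factors, TMM, total counts), the test (edgeR, DESeq2, limma-voom), the filter on low values, the pseudocount (0.1 and 5), the threshold, the Set as a block, and leaving out each library or each Set. The test of Nfat5 alone was an exact 2-sided permutation test of CPM. A paired sign-flip test of its CPM, not named in the fixed design, was added. The labels give no sequencing batch. The gene annotation table at hand describes another assembly and carries no Ensembl identifiers, so it matched 0 identifiers, symbols were taken from the file itself, and no coordinates are given.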

Results

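RNA sequencing was carried out on 8 libraries of primary rat nucleus pulposus cells, the cells of the core of the intervertebral disc. In 4 libraries the cells carried a control vector, and in the other 4 a short hairpin RNA against TonEBP, the transcription factor encoded by Nfat5 that switches on genes protecting cells from salt stress. All 8 cultures had 110 mM NaCl added for 8 h, and each group held 1 library from each of Sets 1 to 4. Control libraries 1 to 4 held 14021533, 9576530, 9567488 and 14743387 reads on the 13613 listed genes, and knockdown libraries 1 to 4 held 15238111, 15782202, 12230914 and 12001853. The 10 most abundant genes took between 5.45% and 11.0% of the reads of a library, and mitochondrial transcripts between 0.379% and 0.922%.

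The comparison asks which genes depend on TonEBP in these cells under hypertonic culture, and the series title names inflammatory genes as its subject. Nfat5 (ENSRNOG00000011879), the target of the hairpin, measured 137, 183, 142 and 66.1 CPM in control libraries 1 to 4 and 86.7, 68.1, 38.8 and 32.2 CPM in knockdown libraries 1 to 4. The knockdown mean was 42.7% of the control mean, and in Sets 1 to 4 the knockdown library held 63.3%, 37.2%, 27.3% and 48.6% of its control. Normalized counts of Nfat5 were 1658 ± 568 in control and 710 ± 329 in knockdown cells (SD, n = 4), a log2 fold change of -1.27 with a standard error of 0.379. The groups overlapped, because control library 4 lay below knockdown library 1. An exact permutation test of the CPM gave p = 0.0857, against a smallest possible value of 0.0286. Limma gave Nfat5 an adjusted p of 0.378 without the Set and 0.0591 with the Set as a block, and DESeq2 with the block gave 9.66e-06. The authors' deposited table gives it a log2 fold change of -1.12 and an adjusted p of 1.21e-05.

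Uap1 fell in the knockdown cells, and a set of cytokine and chemokine genes fell as a group, with 22 of 22 tested members below 0. Osmoprotective genes, such as the sorbitol-producing aldose reductase Akr1b1, and NF-kB pathway genes also fell as groups. Extracellular matrix genes and genes of the p53 response rose as groups, while genes of cholesterol synthesis and of the cell cycle shifted downward by smaller amounts. All of these group calls came from camera with its preset correlation, and each was lost when the correlation between genes was estimated from the 8 libraries, as given for each list.

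Uap1 (ENSRNOG00000002926) encodes the enzyme that makes UDP-N-acetylglucosamine, a sugar donor for glycans. Its normalized counts were 1487 ± 159 in control and 498 ± 54.0 in knockdown cells (SD, n = 4), which is 2.98-fold lower, with a log2 fold change of -1.58, a standard error of 0.141 and a limma adjusted p of 0.0229. It was lower in all 4 Sets, by log2 differences of -1.28, -1.62, -1.68 and -1.73, and the highest knockdown library (559) lay below the lowest control library (1360). No other gene passed in limma: 0 genes were higher and 1 was lower at an adjusted p under 0.05, while 540 higher and 636 lower genes had an unadjusted p under 0.05. Without the Set, edgeR called 0 higher and 1 lower, and DESeq2 called 68 higher and 95 lower. With the Set as a block, limma and edgeR called 0 genes in either direction (2856 and 2763 genes at an unadjusted p under 0.05), limma-voom called 7 higher and 7 lower, and DESeq2 called 518 higher and 656 lower. The limma adjusted p of Uap1 was 0.0578 with the block, and between 0.0771 and 0.227 with any 1 of the 8 libraries left out, so that the call was lost in each case.

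**Figure D1:**
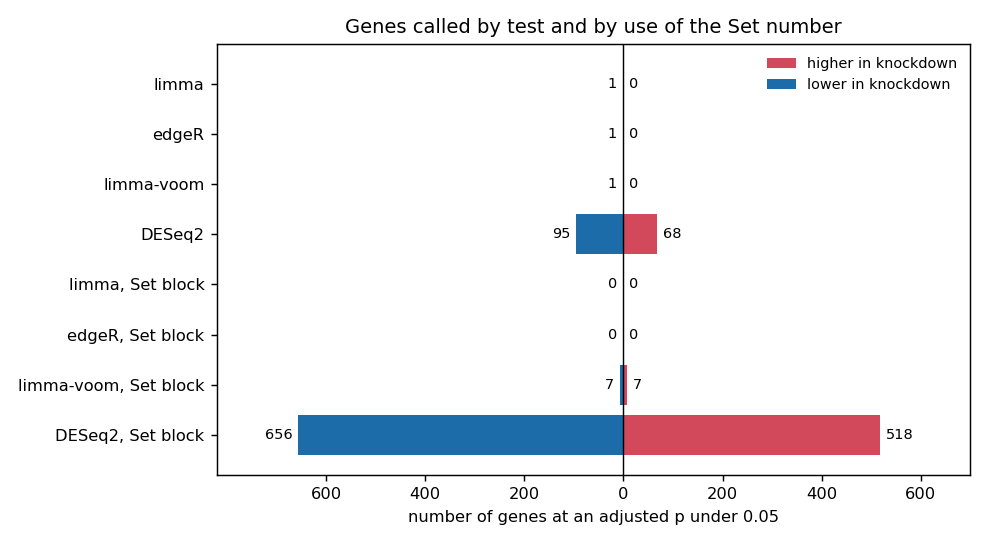
Number of genes called higher (red, to the right) or lower (blue, to the left) in the TonEBP knockdown at an adjusted p under 0.05, for each of 4 tests with and without the Set as a block. The counts run from 0 in either direction (limma and edgeR with the block) to 518 higher and 656 lower (DESeq2 with the block).

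The libraries differed more between Sets than between groups. The first principal component, with 44.8% of the variance, separated Set 1 and Set 2 from Sets 3 and 4, and the second, with 26.3%, separated Set 3 from Set 4. On the first component the control and knockdown libraries lay next to each other for Sets 1 and 2, while those of Sets 3 and 4 were mixed. For 785 of the tested genes (6.34%) the 4 control and 4 knockdown libraries did not overlap. Among the other splits that part the libraries of every Set this count ran from 19 to 153, and it reached 1345 in a split that does not part them all.

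**Figure D2:**
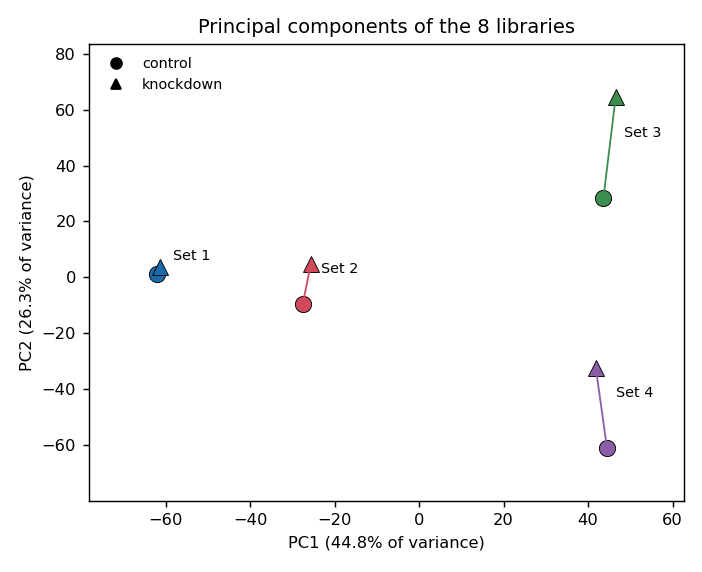
The 8 libraries on the first and second principal components (44.8% and 26.3% of the variance), with circles for control, triangles for knockdown, one colour per Set and a line joining the libraries of a Set. Both libraries of each Set share nearly the same place on the horizontal axis.

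The authors' deposited table lists 501 genes as higher and 639 as lower in the knockdown at an adjusted p under 0.05, and for 413 of these 1140 genes the libraries of the groups did not overlap. Among those 413, the largest rises in the authors' deposited table were Tmem26 (log2 2.06), Fgf21 (1.80), Aldh1l2 (1.57), Sorcs2 (1.43), LOC100912469 (1.40), Chac1 (1.39), Gpr146 (1.25) and Tead2 (1.23). Tmem26 measured 51.9 ± 14.2 normalized counts in control and 300.4 ± 118 in knockdown cells (SD, n = 4). Fgf21, a hormone gene induced by metabolic stress, measured 8.13 ± 9.43 and 106 ± 44.5, and Aldh1l2, a mitochondrial folate enzyme, 299 ± 172 and 1300.2 ± 465 (SD, n = 4). The largest falls among the 413 genes in the authors' deposited table were Itga8 (log2 -1.95), Cxcl10 (-1.82), Il1rn (-1.79), Ifit3 (-1.78), Irg1 (-1.69), Il6 (-1.52), Uap1 (-1.49) and Spp1 (-1.44). Il1rn, the interleukin 1 receptor antagonist, measured 561 ± 161 normalized counts in control and 127 ± 30.8 in knockdown cells, and the integrin gene Itga8 5583 ± 3133 and 1144 ± 760 (SD, n = 4). Spp1, which encodes the matrix protein osteopontin, measured 44114 ± 9846 and 14714 ± 6678 (SD, n = 4). After Uap1, the lowest limma adjusted p values without the Set were 0.144 for Il1rn and 0.236 for Tmem26, and with the block 0.0578 for both.

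**Figure D3:**
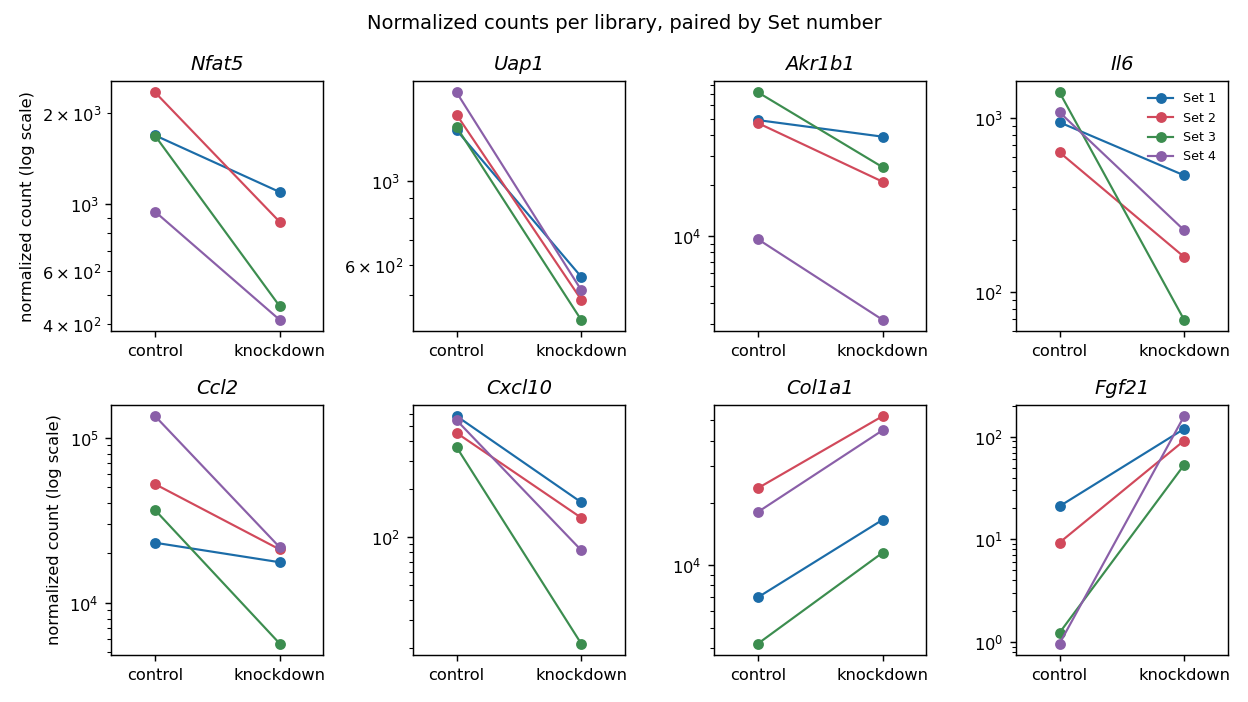
Normalized counts on log axes for 8 named genes in control and knockdown cells, with one line per Set joining its 2 libraries. Every line falls for Nfat5, Uap1, Akr1b1, Il6, Ccl2 and Cxcl10, and every line rises for Col1a1 and Fgf21.

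Of the inflammatory mediators, all 22 tested members had a log2 fold change below 0, with a median of -2.05, and 13 were lower in all 4 Sets. The list fell relative to other genes (camera adjusted p = 8.12e-10), and its adjusted p was 0.776 with an estimated correlation. Il6 measured 1017 ± 318 normalized counts in control and 232 ± 171 in knockdown cells, 5.24-fold lower, with a limma adjusted p of 0.318 without the Set. With the Set as a block its adjusted p was 0.0775 in limma, 0.0846 in edgeR and 1.47e-05 in DESeq2. The monocyte attractant Ccl2 measured 61627 ± 50255 and 16474 ± 7433, and the interferon-inducible chemokine Cxcl10 486 ± 94.7 and 100.4 ± 62.8 (SD, n = 4). Nos2, the inducible nitric oxide synthase, measured 429 ± 697 and 33.8 ± 39.7 (SD, n = 4), and was lower in 3 of 4 Sets. Its control mean was carried by a single library at 1470 (lowest 22.8). Adjusted over all genes tested, 0 members passed in limma. Il6 and Cxcl10 passed when adjusted over the list alone, and with the Set as a block 18 members did. Lower members in the authors' deposited table number 11, with 0 higher, among them Csf2 (log2 -2.30), Cxcl10, Lif (-1.72) and Il6. Tnf and Csf2 were left out of limma by its filter on low reads, with means of 5.73 and 94.1 normalized counts in control and 1.45 and 1.88 in knockdown cells. The control mean of Csf2 was carried by a single library at 362 (SD 179, lowest 0), and DESeq2 with the block, which did not use that filter, gave it an adjusted p of 0.0473. The median of the list differed between Sets, from -0.19 in Set 1 and -1.25 in Set 2 to -3.43 in Set 3 and -3.08 in Set 4, and it was -1.27 without control library 4. Markers of macrophages and leukocytes had a median of -0.55 in the same comparison, and from -1.52 (without knockdown library 1) to -0.10 (without control library 1) with a library left out.

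The NF-kB pathway and feedback genes, many of which answer the same inflammatory signals, had 22 of 26 members below 0 and a median of -0.48 (camera adjusted p = 0.0032). With an estimated correlation the adjusted p was 0.814, and without control library 4 it was 0.212 with the preset one (median -0.22). Without both libraries of Set 3 the call was lost too (camera adjusted p = 0.0741). The authors' deposited table calls 8 members lower and 0 higher, led by Tlr2 (log2 -1.41), Birc3 (-1.20), Tnfaip3 (-1.20) and Traf1 (-1.14). Birc3 measured 1012 ± 806 normalized counts in control and 285 ± 137 in knockdown cells, and the receptor gene Tlr2 8214 ± 8770 and 2035 ± 2162 (SD, n = 4). The control libraries of Tlr2 ran from 1503 to 20950, so a single high library carries much of its control mean. Limma passed 0 of the 26, and 0 when adjusted over the list alone, or 5 with the Set as a block. The interferon response list did not pass (camera adjusted p = 0.307, 18 of 25 members below 0, median -0.15), but without knockdown library 4 it passed downward (0.0123, median -0.44). The authors' deposited table splits its calls, with Ifit3 (log2 -1.78), Oasl (-1.76) and Isg15 (-1.03) lower and Ifit2 (0.78) higher. Adjusted over the list alone, Ifit3 was the member that passed in limma.

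Osmoprotective genes had 12 of 13 tested members below 0 with a median of -0.76 (camera adjusted p = 0.00872), and the adjusted p was 0.814 with an estimated correlation. Akr1b1 measured 44369.7 ± 25775 normalized counts in control and 22254 ± 14845 in knockdown cells (SD, n = 4), a log2 fold change of -1.14 with a standard error of 0.871 and a limma adjusted p of 0.749. The standard error of Akr1b1 was 0.244 with the Set as a block, where its limma adjusted p was 0.0821. The kinase gene Sgk1 measured 1606 ± 1189 and 723 ± 504, the glucose transporter gene Slc2a1 2598 ± 832 and 1595 ± 761, and the ion cotransporter gene Slc12a2 4212 ± 1843 and 2343 ± 1205 (SD, n = 4). The authors' deposited table calls 7 members lower and 0 higher, including Sgk1 (log2 -1.08), Akr1b1 (-0.99), Slc12a2 (-0.82) and Slc2a1 (-0.72). The taurine transporter gene Slc6a6 was close to level, at 3127 ± 1401 and 2779 ± 1412 (SD, n = 4), with a log2 fold change of -0.23 and a limma adjusted p of 0.950, and without knockdown library 4 the log2 fold change turned to 0.29. The betaine transporter gene Slc6a12 had few reads, 49.0 ± 66.6 and 14.9 ± 18.3 normalized counts (SD, n = 4), and a limma adjusted p of 0.887. Limma passed 0 of the 13 members, over all genes and adjusted over the list alone, and 8 of them over the list alone with the Set as a block. The call of the list was lost without control library 2 (camera adjusted p = 0.0723, median -0.37), control library 3 (0.0960) or knockdown library 4 (0.176), and without both libraries of Set 3 (0.0905).

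Heat shock chaperones had 14 of 17 tested members below 0 with a median of -0.19, which did not pass without the Set (camera adjusted p = 0.277) and passed with the Set as a block (0.0486). Without the Set it passed when control library 4 (0.0287, median -0.30) or knockdown library 1 (0.0291, median -0.39) was left out. With the block and an estimated correlation its camera adjusted p was 0.641. The authors' deposited table lists Hsph1 (log2 -0.78), Hspb8 (-0.60), Hspa4 (-0.44) and Hspa4l (-0.70) as lower, and Bag3 (0.47) as higher. Hypoxia and glycolysis genes went both ways, 14 above and 10 below 0 (camera adjusted p = 0.978), and their mean of -0.04 and median of 0.08 differ in sign. The authors' deposited table calls 6 of them lower, including Pgam1 (log2 -0.93), Vegfa (-0.96) and Egln3 (-0.91), and 4 higher, including the glycolytic enzyme gene Pfkl (0.42), with P4ha1, Car9 and Pdk1.

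Extracellular matrix genes had 18 of 25 tested members above 0 with a median of 0.45 (camera adjusted p = 0.00878), and the adjusted p was 0.814 with an estimated correlation. The type I collagen gene Col1a1 measured 13230.2 ± 9155 normalized counts in control and 31358 ± 20325 in knockdown cells (SD, n = 4), a log2 fold change of 1.29 with a standard error of 0.673 and a limma adjusted p of 0.592. Per Set its log2 differences were 1.24, 1.15, 1.46 and 1.31, and its standard error with the Set as a block was 0.142. Its adjusted p with the block was 0.0578 in limma, 0.0605 in edgeR and 1.01e-19 in DESeq2. Matn4, a matrix adaptor protein gene, measured 126 ± 102 and 397 ± 219, and the type V collagen gene Col5a1 5055 ± 1773 and 9960 ± 2332 (SD, n = 4). The authors' deposited table calls 8 members higher and 0 lower, among them Matn4 (log2 1.60), Col1a1 (1.24), Col5a1 (0.95) and Col1a2 (0.88). Limma passed 0 of the 25, and 0 adjusted over the list alone, or 7 with the Set as a block. The median was -0.17 in Set 3 and between 0.52 and 0.56 in the other Sets. With a library left out it ran from 0.24 (without control library 4) to 0.81 (without knockdown library 3), and the call was lost without control library 1 (camera adjusted p = 0.0705), control library 3 (0.124), knockdown library 2 (0.0931) or knockdown library 4 (0.104). The call was also lost without both libraries of Set 1 (camera adjusted p = 0.133) or of Set 4 (0.0700).

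Matrix proteases and their inhibitors did not move together (12 above and 14 below 0, median -0.04, camera adjusted p = 0.740), and their median and mean lay below 0 while camera ranked the list upward. The authors' deposited table lists 5 as higher, Mmp11 (log2 1.29), Adamts2 (1.16) and the membrane collagenase Mmp14 (0.85) beside Adamts12 and Mmp19, and 4 as lower, Mmp10 (-1.31), Mmp13 (-1.22), Mmp9 (-0.92) and the inhibitor Timp1 (-0.92). Mmp10, a stromelysin, measured 35314 ± 62774 normalized counts in control and 4400 ± 5123 in knockdown cells (SD, n = 4), with the control value carried by library 4 at 129407. Glycosaminoglycan synthesis genes had 10 of 23 members above 0 (median -0.09, camera adjusted p = 0.928). The authors' deposited table lists 4 of them as lower, B4galt7 (log2 -0.85), Chst15 (-0.76), Ugdh (-0.75) and Chst11 (-0.52), and 2 as higher, Chpf (0.67) and B3gat3 (0.62). Ugdh, which makes the UDP-glucuronate used in these chains, measured 5817 ± 4100 and 3020 ± 1340 normalized counts (SD, n = 4).

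**Figure D4:**
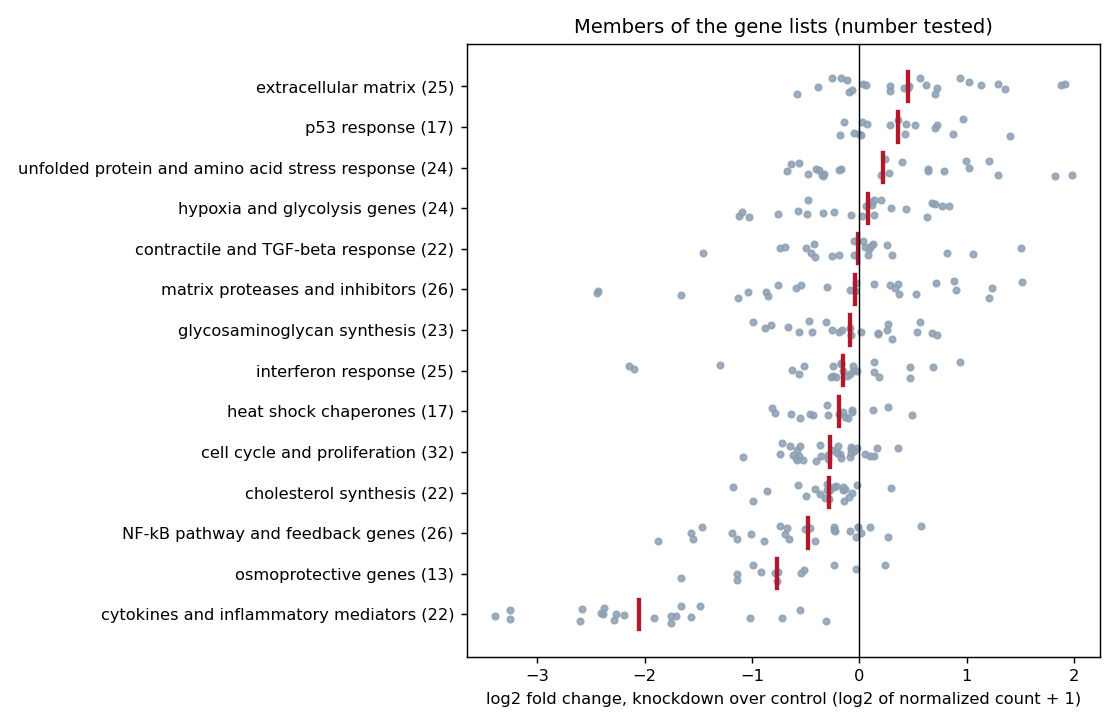
Log2 fold changes, knockdown over control, of the tested members of the 14 pathway lists (points) and each list's median (red bar), on the log2(normalized count + 1) scale. The medians run from -2.05 for cytokines and inflammatory mediators to 0.45 for extracellular matrix genes.

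The p53 response list had 13 of 17 members above 0 and a median of 0.36 (camera adjusted p = 0.00939), with an adjusted p of 0.814 at an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, measured 4647 ± 1936 normalized counts in control and 8530 ± 1678 in knockdown cells, and the pro-apoptotic gene Pmaip1 220 ± 76.1 and 393 ± 74.6 (SD, n = 4). The authors' deposited table lists 4 of the 17 as higher, Cdkn1a (log2 0.80), Pmaip1 (0.76), Gadd45a (0.66) and Bbc3 (0.64), and 0 as lower. The call of this list was lost without control library 2 (camera adjusted p = 0.0723), control library 3 (0.224, median 0.21) or knockdown library 4 (0.104). It was also lost without both libraries of Set 3 (camera adjusted p = 0.378, median 0.19). Cell cycle genes had 27 of 32 members below 0 with a median of -0.27 (camera adjusted p = 0.00939), and the adjusted p was 0.887 with an estimated correlation. The authors' deposited table calls 0 of them, and the member with the lowest p, the nucleotide synthesis gene Tyms, measured 286 ± 74.9 and 189 ± 20.8 (SD, n = 4). The median of the cell cycle list was 0.29 in Set 1 and negative in the other Sets, and its call was lost without control library 3 (camera adjusted p = 0.715, median -0.05) or knockdown library 4 (0.328). Leaving out both libraries of Set 3 (camera adjusted p = 0.151) or of Set 4 (0.0999) lost it as well. Limma passed 0 members of the p53 list and 0 of the cell cycle list, over all genes or adjusted over the list alone, and with the Set as a block 4 of the former and 0 of the latter over the list alone.

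Cholesterol synthesis genes had 21 of 22 members below 0 with a median of -0.28 (camera adjusted p = 0.00155), and the adjusted p was 0.776 with an estimated correlation. Ebp measured 142 ± 19.1 normalized counts in control and 73.5 ± 25.5 in knockdown cells, and Hsd17b7 144 ± 23.0 and 80.7 ± 22.6 (SD, n = 4). Both encode late enzymes of the pathway, and both are lower in the authors' deposited table (log2 -0.81 and -0.73), which calls no further member. Limma passed 0 of the 22 over all genes and 0 adjusted over the list alone, and the median was 0.12 in Set 3. Without control library 4 the median was -0.16 (camera adjusted p = 0.0420), and the call was lost without both libraries of Set 4 (0.111). The joint list of unfolded protein and amino acid stress genes did not pass (13 of 24 above 0, camera adjusted p = 0.740). In the authors' deposited table Chac1 (log2 1.39), Trib3 (1.08), Sesn2 (1.06) and Phgdh (0.92) are higher and Hsp90b1 (-0.59) is lower. Chac1, which degrades glutathione, measured 62.4 ± 34.4 and 223 ± 47.3 normalized counts (SD, n = 4), and it was the member of that list that passed in limma when adjusted over the list alone. Contractile and TGF-beta response genes had 11 members above and 11 below 0 (camera adjusted p = 0.857), and Tgfbi (log2 0.87), Tgfb2 (0.81) and Loxl2 (0.73) are higher in the authors' deposited table.

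None of the 7 marker lists passed in camera without or with the Set as a block. With a library left out, the median of the nucleus pulposus and of the fibroblast list changed sign. The 13 tested nucleus pulposus markers had a median of -0.05 (camera adjusted p = 0.978), and 0 of them passed in limma or in the authors' deposited table. Hif1a, the member with the lowest p, measured 6372 ± 1545 normalized counts in control and 5696 ± 1621 in knockdown cells (SD, n = 4). The list of annulus fibrosus and fibroblast markers had 7 members above and 7 below 0 (camera adjusted p = 0.767), and its tendon-related member Scx measured 399 ± 108 and 565 ± 124 (SD, n = 4). For these lists and for the contractile list the median lay just below 0 while camera ranked the list upward. Chondrocyte markers had a median of 0.53 over 5 members (camera adjusted p = 0.176), with Ucma and Pth1r (log2 1.02) higher and Ibsp (-1.34) lower in the authors' deposited table. The 6 macrophage and leukocyte markers had a median of -0.55 (camera adjusted p = 0.462), and Cd68 ranged from 19.9 to 213 normalized counts in control and from 14.5 to 96.9 in knockdown libraries. Cd68 was lower in all 4 Sets and is the only member called in the authors' deposited table, where it is lower (log2 -0.94, adjusted p 0.0178). The 4 endothelial markers had a median of -0.13 (camera adjusted p = 0.709), and Flt1, a receptor gene for vascular growth factor, measured 201 ± 109 and 72.4 ± 27.9 (SD, n = 4) and passed in limma when adjusted over the list alone. The single erythroid marker tested, Ahsp, measured 20.6 ± 3.58 and 21.2 ± 13.9 (SD, n = 4; camera adjusted p = 0.928). The 8 mitochondrial transcripts, a sign of RNA quality, had a median of 0.10 (camera adjusted p = 0.634), and from -0.21 (without control library 1) to 0.31 (without control library 2) with a library left out, and Mt-nd2 measured 118 ± 41.2 and 175 ± 67.6 (SD, n = 4).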

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

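Of the tests in this part, those of leukocyte markers, of leaving out a Set, of other scalings and of other splits for the cytokine list were chosen after the result of that list was seen.

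Single libraries stood apart from the other 3 of their group for 12 of the 166 groups of values examined, where chance gives about 1 in 20. These were the 78 genes named by the rule and 5 measures of the libraries, each in both groups, and all 12 were genes. Each number given here is the gap from that library to its nearest neighbour as a share of the group's range, on the log2 scale. Control library 4 was the highest for Ibsp (0.964, with 496 normalized counts against 12.3 in the next library), Traf1 (0.959) and Lif (0.868, with 3006 against 209). Control library 3 was the highest for Isg15 (0.843). Knockdown library 1 was the highest for Cd68 (0.854), for Hspb8 (0.839) and for Tnf (1, the other 3 libraries being at 0), and the lowest for Aldh1l2 (0.878, with 613 against 1458). Knockdown library 4 was the highest for Trib3 (0.880) and for Csf2 (1, the other 3 being at 0), knockdown library 2 the lowest for Tyms (0.915), and knockdown library 3 the lowest for Ccl2 (0.844, with 5655 against 17572).

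The cytokine and inflammatory mediator list lay below 0 for 22 of 22 tested members, with a high control value for its member Lif in library 4. A single Set as the cause is argued against, with a list median no higher than -1.49 when any Set was left out. Scaling is argued against too, since a factor moves all genes of a library alike. The list median was -2.03 or lower under total counts and TMM, while that of the extracellular matrix list was 0.45. The median of all tested genes (0.0004) is held near 0 by the size factors themselves, so it does not bear on this. Fewer leukocytes in the knockdown cultures stay open, because the median of the leukocyte markers lay 1.502 above that of the cytokine list (standard error 0.313) but 0.297 above it without control library 4 (0.281) and 0.693 without knockdown library 1 (0.468). These standard errors are those of a difference of means over list members taken as independent, and do not measure the spread between libraries. Chance stays open as well: the size of the median (2.05) was reached in 1 of the 35 splits of the 8 libraries, the real one (highest other 1.90), but the Sets pair the libraries, and the 8 splits that part every Set (highest other 1.70) are too few for a share under 0.05.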

How the results depend on the processing

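Tests with the Set as a block in DESeq2, limma-voom, camera with an estimated correlation or fry, the looser threshold, TMM in limma, edgeR with TMM and without the block, the lists without both libraries of a Set, and the standard error ratio were chosen after the data were seen. The count of genes lower in the knockdown was 1 in limma and 0 with the replicate block in limma and in edgeR, 0 at an adjusted p under 0.01, and 0 (lowest) to 0 (highest) with any library or any Set left out, where the smaller number of libraries is part of the cause. DESeq2 called 68 higher and 95 lower, and with the block 518 and 656, of which 1116 are also called in the authors' deposited table. With the block, limma-voom called 7 higher and 7 lower, and limma at an adjusted p under 0.10 called 311 and 387. Other scalings, filters and pseudocounts left Uap1 called. Nfat5 was negative in every setting, and its adjusted p was under 0.05 only in DESeq2 with the block (log2 -1.27, adjusted p 9.66e-06, against 0.0539 to 0.999 in the other settings). Camera called 7 gene lists, 0 with an estimated correlation, 0 with fry, and 0 with either when the block was added. These fry counts are for movement on balance one way. For changes in either direction, the lowest fry adjusted p without the block was 0.277. With the block, fry for either direction passed some lists, such as heat shock chaperones (6.02e-05), but not the cytokine list (0.0802). With libraries left out camera called from 3 to 8 lists. It called 3 without control library 3 and 3 without Set 3, and 4 without knockdown library 4 and 4 without Set 4. The cytokine list was called in each of these. In camera with the preset correlation the block added the heat shock call and changed no other list call. Slc6a6 ranged from -0.67 to 0.29 with libraries left out and turned positive without knockdown library 4. The Ahsp log2 fold change, not called in any setting, ranged from -0.49 to 0.12 with libraries left out, and was 0.0372 in edgeR with DESeq2 size factors and 0.0314 in edgeR with TMM. The cause of these reversals was not tested.

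Limma called as many genes as the real split in 2 of the 35 splits of the 8 libraries, so chance cannot be excluded for that count. The real value was 1 and the highest other 242, from Sets 1 and 2 against Sets 3 and 4, which points to a structure of the samples by Set. Among the other splits that part the libraries of every Set the highest was 0. Camera called as many gene lists in 10 of the 35 splits (real value 7, highest other 10, and 7 among the others that part every Set), so chance cannot be excluded for the number of lists. For DESeq2 with the block, the 8 splits that part every Set are too few for a share under 0.05. There 1 of 8 splits, the real one, reached 1174 genes, and the highest other called 19. Genes that DESeq2 called on 3 Sets kept their direction in the Set left out for 83.8% to 98.6% of genes. This argues against noise that strikes genes independently within Sets as the source of the calls. Noise shared by many genes of a library could also raise such shares, and this check was not run on the other splits. The standard error of a gene without the Set, divided by that with it, had a median over genes of 1.47. This value lies between the bounds set for this test, so how far the spread between Sets explains the low count without the block stays open.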

Other observations

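All tests in this part were chosen after the results were seen, and so were the genes named by branch.

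In the list of unfolded protein and amino acid stress genes, 2 branches had medians of opposite sign. All 12 members of the amino acid branch had a log2 fold change above 0, with a median of 0.89, including the transcription factor genes Atf4 (0.79) and Ddit3 (1.02), the serine synthesis gene Phgdh (1.204) and the asparagine synthetase gene Asns (0.40). Of the 12 members placed in the endoplasmic reticulum branch, 1 lay above 0, Herpud1 (0.28). The median of that branch was -0.36, with Hspa5, the chaperone BiP, at -0.41 and Hsp90b1 at -0.64. Of the amino acid members 4 are higher and 0 lower in the authors' deposited table, against 0 higher and 1 lower in the other branch, and Slc7a11, at 0.64 here, is at -0.25 there. None of these genes passed in limma over all genes, without the Set or with it as a block.

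The list was parted into branches after its values were seen. A 2-sided permutation test of the difference of 1.25 between the medians (p = 0.00021) used the same values, so it restates the difference and lends it no further weight. Fgf21, Aldh1l2 and Chac1, which are known targets of Atf4, are among the largest rises in the authors' deposited table for genes whose groups did not overlap. They were picked after that ranking was seen, and targets of Atf4 were not tested as a set. No technical explanation was tested for this split, and the members were placed in branches from textbook knowledge.

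Uap1 ends the hexosamine route that makes UDP-N-acetylglucosamine. A fall of the whole route with it was tested on 8 other measured genes of the route and of its use. Their median log2 fold change was 0.012, and the standard error of their mean, from the spread over genes, was 0.174. They went both ways. Below 0 were Gfpt2 at -1.0001, Nagk at -0.45, Gnpnat1 at -0.27 and Gfpt1 at -0.02. Above 0 were Mgea5 at 0.52, Uap1l1 at 0.45, Pgm3 at 0.08 and Ogt at 0.04. For Gfpt2 the limma standard error was 1.19 without the Set and 0.236 with the Set as a block. With the block the lowest limma adjusted p values were 0.0924 for Gfpt2, 0.117 for Nagk and 0.132 for Mgea5. Without Ogt and Mgea5, which use the sugar or remove it from proteins, the median of the other 6 was -0.142, with a standard error of their mean of 0.203. A fall of the part that makes the sugar therefore stays open.

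The size of the response differed between Sets. For genes that DESeq2 with the block called on the other 3 Sets, the median change in the direction of those Sets was 0.35 in Set 1, 0.94 in Set 2, 0.80 in Set 3 and 1.09 in Set 4, while the log2 change of Nfat5 was -0.62, -1.42, -1.87 and -1.18. Whether the response follows the depth of the knockdown cannot be told apart from chance with 4 Sets, since the exact permutation p was 0.917 and the smallest possible value is 0.0833.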
